A study of Mus musculus with 12 samples.

How the data were processed

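Bulk RNA sequencing was done on cells recovered by peritoneal lavage from C57BL/6J mice. Each of the 3 groups holds 4 libraries: mice injected with the line labelled ID8 (defb29/Vegf-a), called ID8 here, mice injected with that line carrying the follicle-stimulating hormone receptor, labelled ID8 (defb29/Vegf-a) FSHR and called ID8-FSHR here, and mice that received no injection. Groups and replicate numbers were taken from the labels, and the submitters call the samples of a group biological replicates. The sample titles of the ID8-FSHR group skip numbers, and the labels do not say why. Whether other mice of that group were left out is therefore not known. Lavage was done 7 days after injection, and RNA was extracted with a column kit and turned into libraries after depletion of ribosomal RNA, per the labels.

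The deposited table holds whole-number read counts per gene for 55401 Ensembl gene identifiers with symbols, 1 column per library, and the authors did not normalize them as far as the labels and the values show. Per the submitters' processing notes, the tools were bcl2fastq 2.20, STAR 2.7.9a and featureCounts from Subread 1.6.4 on the mouse build GRCm38.p6. The strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Counts of genes that overlap another gene, and of genes with near-identical copies, are therefore uncertain.

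The total count per library ran from 47419608 to 64333677. A gene with 0 counts in a library was given an upper limit of 3 counts, which is 0.0444 to 0.0653 CPM (counts scaled by the effective library size) across the 12 libraries. Such limits and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries within a group agreed within sampling noise.

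Differences were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 (robust fit) on the deposited counts of all 12 libraries. The model held the group only, scaling was by trimmed mean of M values (TMM), and low counts were removed with edgeR's default filter, which left 16915 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 are described as higher or lower, or as having risen or fallen. Fold changes are given on the log2 scale with the standard error (SE) of the fit, and levels as mean CPM ± standard deviation (SD). Where every library of a group had 0 counts, the fold was computed against 3 counts over that group and is a lower bound. For symbols carried by more than 1 gene (217 symbols) the identifier was kept.

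Lists of marker genes for 18 cell types and 24 other gene groups were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of their symbols, 646 matched the table, 2 matched several genes and were not used, and 1 did not match. Each of the 40 lists with at least 3 tested members was tested in each comparison with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 40 lists. Camera with an estimated correlation and fry, which asks whether a list's genes moved on balance in 1 direction, were run beside it. Member counts were made over all tested genes and adjusted over the list alone. The level of a list in a library is the mean over its members of log2 of CPM plus 0.5, minus the mean of the uninjected group. For members near 0 CPM in uninjected mice the added 0.5 limits the level.

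By the rule for named genes, the text gives Fshr, Defb29 and Vegfa, and in each comparison the 8 largest increases and 8 largest decreases. These were taken among genes past the threshold with a mean log2 CPM of at least 3, a symbol other than that of a predicted model, and groups that do not overlap. To these were added up to 3 members, those with the smallest adjusted p, of each of the 8 lists with the smallest camera p. A count of 5 or fewer genes could be named in full. Some genes that the rule takes are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

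Calls shared by both tumour groups against the uninjected mice were set beside 20 simulations with unchanged groups, beside the overlap of independent lists, and beside 6 splits of the uninjected libraries into 2 and 2. The alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios size factors, no filter, a filter of 1 CPM in 4 libraries, a fit of only the groups compared, leaving out the 10 most abundant genes, stricter thresholds, a block for the replicate number, and leaving out each library in turn. Added after the data were seen were a fit of the 8 tumour libraries with the Defb29 level as a covariate, list tests over those 8 libraries without it, and list tests without ID8-FSHR replicate 2. The closing section gives their effect.

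The test was tried on simulated data with 200 genes changed by known factors. For ID8-FSHR versus ID8 it recovered 29.9% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 74.2% of those changed 4-fold, with 6 unchanged genes called. For ID8 versus no injection the shares were 26.9%, 65.7% and 80.3%, with 9 unchanged genes called, and for ID8-FSHR versus no injection 37.3%, 59.7% and 81.8%, with 4. Gene positions are from the GENCODE M21 annotation of GRCm38, in which 54349 of the 55401 identifiers matched with their version and 55141 without it. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.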

Results

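RNA was sequenced from cells washed out of the peritoneal cavity of C57BL/6J mice with 8 mL of buffered saline, 7 days after an intraperitoneal injection of tumour cells. ID8 is a mouse ovarian surface epithelial cancer line, used here as its derivative that overexpresses the beta-defensin Defb29 and the vascular growth factor Vegfa, and ID8-FSHR is that line with the follicle-stimulating hormone receptor added, per the labels. A lavage contains resident and recruited immune cells together with any tumour cells that float in the cavity, so every value below is a level in a mixture of cells. The 3 groups of 4 libraries were ID8, ID8-FSHR and no injection. The number of cells injected is given as 4000000 in the series text and as 5000000 in the sample protocol, and these were not reconciled. Total counts per library ranged from 47419608 to 64333677 in ID8, from 48355885 to 57636459 in ID8-FSHR and from 50327658 to 57991979 in the uninjected mice. The most abundant transcript, the ribosomal RNA gene CT010467.1, took 4.12% of all counts. The share of the 10 most abundant genes was 15.2% ± 0.424 (SD, n = 4) in uninjected mice, 10.6% ± 0.861 in ID8 and 10.2% ± 1.25 in ID8-FSHR.

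The receptor that distinguishes the tumour groups by label was read first. Fshr (ENSMUSG00000032937.5, chromosome 17, 88984952 to 89200675 on the minus strand of GRCm38, 10 exons after merging) had 7 counts in ID8-FSHR replicate 4, 2 counts in ID8-FSHR replicate 3, 2 counts in ID8 replicate 3 and 0 counts in every other library. It fell below the filter on low counts, and the ratio of ID8-FSHR to ID8 was 4.63 (95% exact binomial interval 0.958 to 44.0). This row therefore does not check the label. A construct that lacks the mouse exons would not be counted in it, and the construct's sequence is not given in the sources used here. ID8-FSHR below means the libraries labelled ID8-FSHR. The other added genes were present in both tumour groups. Defb29 (ENSMUSG00000044249.3, chromosome 2, 152538714 to 152540098, minus strand) stood at 26.2 ± 3.76 CPM in ID8 and 18.5 ± 6.88 CPM in ID8-FSHR (SD, n = 4 each) against 0 counts in all 4 uninjected libraries. That is at least 1757-fold and at least 1257-fold higher, with the uninjected group at its limit of 3 counts. Vegfa (ENSMUSG00000023951.18, chromosome 17, 46016993 to 46032369, minus strand) stood at 52.3 ± 4.72 and 62.2 ± 18.2 CPM against 1.94 ± 0.411 CPM, 26.9-fold (edgeR adjusted p = 3.61e-09) and 32.0-fold (edgeR adjusted p = 3.39e-09) higher.

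The first principal component, 81.0% of the variance of log2 CPM, separated the uninjected libraries from the tumour libraries, and the next, 5.62%, ordered the tumour libraries. ID8-FSHR replicate 2 stood apart, at -43.2 on the first component where the other 7 tumour libraries lay between -96.1 and -87.4. Its mean correlation with the uninjected libraries was 0.877, against 0.823 to 0.835 in the other tumour libraries.

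**Figure D1:**
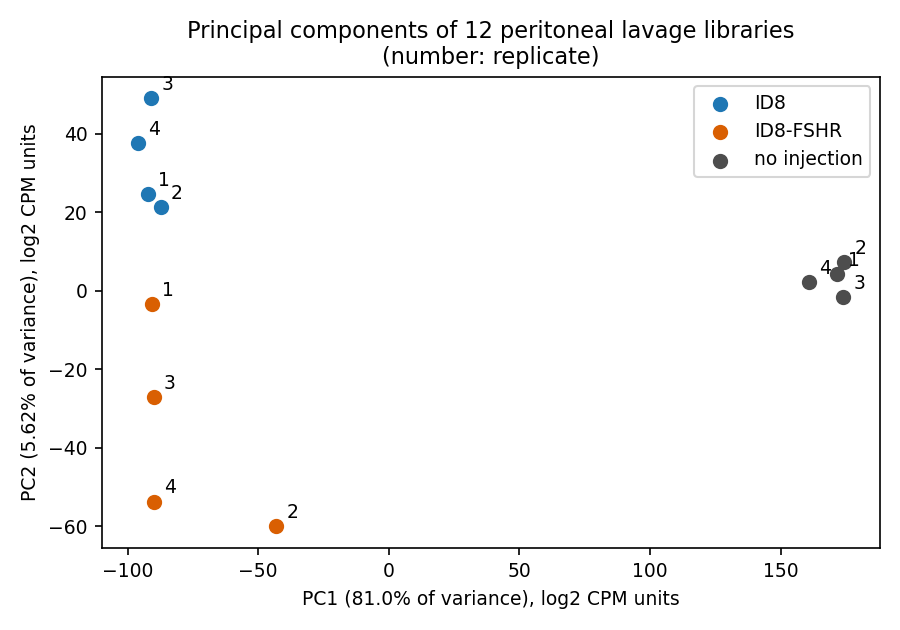
Principal components of log2 CPM for the 12 libraries, 1 point per library, coloured by group and numbered by replicate. The uninjected libraries sit at 161 to 174 on the first component (81.0% of the variance) and the tumour libraries at -96.1 to -43.2, with ID8-FSHR replicate 2 nearest the uninjected libraries.

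ID8 against no injection asks how lavage RNA differs after injection of ID8 tumour cells. No group was injected without tumour cells, so the tumour cannot be told apart from the injection. CPM are shares of a mixture, so a fall in genes of host cells was not separated from dilution by tumour RNA. Of the 15 mesothelial genes 14 were higher in lavage from ID8-injected mice, while all 15 B cell genes and 13 of 18 markers of resident macrophages were lower. With an estimated correlation these lists had an adjusted p = 0.176, adjusted p = 0.332 and adjusted p = 0.75. Wt1, a transcription factor of mesothelium and ovarian surface epithelium, stood at 550.1 ± 43.0 CPM against 0.404 ± 0.225 CPM (SD, n = 4 each), 1378-fold higher (edgeR adjusted p = 1.09e-09). Cd79b, a signalling chain of the B cell receptor, fell from 432 ± 46.7 to 57.0 ± 9.97 CPM, a log2 fold change of -2.92 (SE 0.16, edgeR adjusted p = 8.04e-09). In all, 5537 genes were higher and 5310 lower of the 16915 tested, and for 62.5% of the tested genes the 4 values of the groups did not overlap, where chance gives 2.86%. Among the genes that rose, 416 had 0 counts in every uninjected library.

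Among the 15 mesothelial genes 14 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change of 6.57 (camera adjusted p = 2.48e-14, and adjusted p = 0.176 with an estimated correlation). Krt19, an intermediate filament keratin, rose from 1.29 ± 0.767 to 705 ± 69.8 CPM (552-fold), and Gpm6a, a membrane glycoprotein, from 4.07 ± 0.812 to 350 ± 36.6 CPM (85.9-fold). The epithelial and ID8 tumour list shares 3 keratins with it. There 7 of 13 tested genes rose (8 adjusted over the list alone) and 4 fell, among them Epcam, Sfn and Cdkn2a (camera adjusted p = 0.00606, and adjusted p = 0.332 with an estimated correlation). Fibroblast genes rose in 10 of 13 and fell in 1, Thy1, with the same counts adjusted over the list alone (median 3.22, camera adjusted p = 0.00501, and adjusted p = 0.581 with an estimated correlation). Of 18 tested extracellular matrix and mesenchymal genes 12 rose and 5 fell, likewise over the list alone (median 5.66, camera adjusted p = 0.0256, and adjusted p = 0.546 with an estimated correlation). The 5 were the transcription factors Zeb1 and Zeb2, Tgfb1, and Fn1 and Tgfbi, matrix proteins that peritoneal macrophages also make. The largest increases were in Pkhd1l1, which reached 4322 ± 445 CPM from 1.34 ± 0.226 (log2 fold change 11.66, SE 0.43), Tm4sf1 (11.08, SE 0.65), the heparan sulfate endosulfatase Sulf1 (10.75, SE 0.40), Wt1, Plce1, the secreted chaperone Clu, Ildr2 and the semaphorin Sema3d (9.91, SE 0.50).

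The FSH and cAMP list holds genes of gonadal steroid synthesis and of the cAMP response. Of its 19 tested genes 14 rose and 4 fell, over all genes and adjusted over the list alone (median 2.68, camera adjusted p = 8.58e-05, and adjusted p = 0.332 with an estimated correlation). Star, which brings cholesterol into mitochondria for steroid synthesis, rose 97.4-fold to 147 ± 15.8 CPM. Inhbb, a subunit of inhibin B and activin B, rose 577-fold to 41.6 ± 1.25 CPM, and the epidermal growth factor family ligand Btc rose 49.6-fold to 35.6 ± 6.68 CPM. Those that fell were Cyp11a1, Pde4b, Prkar2b and Sik1. Targets of p53 rose in 10 of 14 and fell in 1, Fas, with the same counts adjusted over the list alone (median 0.91, camera adjusted p = 8.58e-05, and adjusted p = 0.0723 with an estimated correlation). The cell cycle inhibitor Cdkn1a went from 44.7 ± 3.98 to 155 ± 4.30 CPM. Phlda3 rose 17.8-fold to 39.1 ± 2.85 CPM and the death receptor Eda2r from 0.0606 ± 0.0525 to 38.0 ± 4.72 CPM. All 20 genes of G2/M and mitosis rose (20 adjusted over the list alone, median 1.53, camera adjusted p = 0.000429), among them the motor protein Kif11 at 3.06-fold and the mitotic kinase Cdk1 at 4.63-fold. Genes of G1/S and DNA replication rose in 17 of 20, with 1, Ccne1, lower (17 and 1 adjusted over the list alone, median 1.20, camera adjusted p = 0.000953). The thymidylate synthase Tyms rose 2.76-fold. Both cell cycle lists had an adjusted p = 0.75 with an estimated correlation.

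All 15 B cell genes fell, also when adjusted over the list alone (median -2.79, camera adjusted p = 6.3e-14, and adjusted p = 0.332 with an estimated correlation). Besides Cd79b these included the scaffold protein Bank1, from 401.5 ± 41.6 to 76.2 ± 5.05 CPM, and the transcription factor Spib, from 221 ± 25.9 to 27.8 ± 3.75 CPM. Genes that mark B-1 cells, the innate-like B cells of the peritoneum, fell in 11 of 12, with Myof higher (the same counts adjusted over the list alone, median -2.27, camera adjusted p = 8.58e-05, and adjusted p = 0.22 with an estimated correlation). Siglecg, an inhibitory receptor of B-1 cells, fell 8.77-fold and Zbtb32 9.25-fold. The immunoglobulin variable segments Ighv11-2 (log2 fold change -4.17, SE 0.27) and Igkv14-126 (-4.09, SE 0.28) fell the most. They were followed by the calcium channel gene Cacna1e, from 268 ± 31.5 to 15.9 ± 3.95 CPM (-4.07, SE 0.22), Dnase1l3, Diras2, the interleukin 5 receptor chain Il5ra (-3.68, SE 0.24), the basement membrane protein Nid1 and Rdh12. Variable segments resemble one another, and reads may have been shared between them.

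Markers of large peritoneal macrophages, the resident macrophages of the cavity, fell in 13 of 18 (16 adjusted over the list alone), and their defining transcription factor Gata6 rose (log2 fold change 0.85). The list had a median of -0.91 (camera adjusted p = 0.00754, and adjusted p = 0.75 with an estimated correlation). MHC class II genes, which present antigen on macrophages, dendritic cells and B cells, fell in 11 of 12 (11 adjusted over the list alone, median -0.96, camera adjusted p = 0.000953, and adjusted p = 0.75 with an estimated correlation). All 20 ribosomal protein genes fell (20 adjusted over the list alone, median -0.91, camera adjusted p = 3.89e-11, and adjusted p = 0.447 with an estimated correlation). Rpl13 went from 704 ± 40.9 to 347 ± 9.18 CPM. Such genes have many processed copies in the genome, so the split of their reads is uncertain. Of the 13 lists that camera called, 0 passed with an estimated correlation and 13 passed with fry.

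ID8-FSHR against no injection puts the same question to the tumour labelled as carrying the receptor. All 20 genes of G2/M and mitosis, 14 of 15 mesothelial genes and 14 of 19 FSH and cAMP genes were higher, while all 15 B cell genes, 10 of 12 B-1 cell genes and all 20 ribosomal protein genes were lower. With an estimated correlation these lists had an adjusted p = 0.28, and ribosomal protein genes an adjusted p = 0.452. Top2a, a topoisomerase of dividing cells, stood at 503 ± 75.7 CPM against 47.2 ± 10.2 CPM (SD, n = 4 each), a log2 fold change of 3.42 (SE 0.19, edgeR adjusted p = 1.29e-08). Blk, a kinase of the B cell receptor pathway, fell from 183 ± 14.2 to 14.7 ± 3.60 CPM (log2 fold change -3.63, SE 0.20, edgeR adjusted p = 8.68e-09). In all, 5735 genes were higher and 5178 lower, and the groups did not overlap for 57.1% of the tested genes, where chance gives 2.86%.

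All 20 G2/M and mitosis genes rose (median 3.40, camera adjusted p = 5.11e-17), as did 19 of 20 genes of G1/S and DNA replication (median 2.40, camera adjusted p = 4.51e-15), with the same counts adjusted over the list alone. Hmmr rose 14.0-fold, Kif11 reached 89.3 ± 12.2 from 8.15 ± 1.70 CPM, and the increases were 6.61-fold for Tyms and 5.65-fold for the replicative helicase subunit Mcm3. Mesothelial genes rose in 14 of 15 (median 6.02, camera adjusted p = 3.18e-12), with Wt1 at 371 ± 125 CPM, Krt18 at 371 ± 139 CPM and Krt19 at 320 ± 108 CPM. Of the FSH and cAMP genes 14 rose and 3 fell, Cyp11a1, Pde4b and Prkar2b (median 2.28, camera adjusted p = 0.000122). Star stood at 107 ± 37.4 CPM, Inhbb at 36.7 ± 9.40 CPM and Nr5a1, a nuclear receptor of steroid-producing cells, at 32.1 ± 8.82 CPM against 0.0545 ± 0.109. Epithelial and ID8 tumour genes rose in 8 of 13 and fell in 3 (median 3.16, camera adjusted p = 0.0108), and p53 targets rose in 9 of 14 and fell in 2, Bbc3 and Fas (median 0.60, camera adjusted p = 0.0195). These 4 lists also kept their counts adjusted over the list alone. Each list of this paragraph had an adjusted p = 0.28 with an estimated correlation.

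Fibroblast genes rose in 9 of 13 (9 adjusted over the list alone, median 2.83, camera adjusted p = 0.00555, and adjusted p = 0.449 with an estimated correlation). Without ID8-FSHR replicate 2 the camera adjusted p was 0.0799. Extracellular matrix and mesenchymal genes rose in 12 of 18 and fell in 5 (the same adjusted over the list alone, median 4.78, camera adjusted p = 0.0473, and adjusted p = 0.492 with an estimated correlation). That call was lost without ID8-FSHR replicate 2 (adjusted p = 0.123), without ID8-FSHR replicate 4 (0.0623) and with median-of-ratios size factors (0.0553). Genes of the type I interferon response rose in 18 of 22 (19 adjusted over the list alone, median 2.08, camera adjusted p = 0.0487, and adjusted p = 0.825 with an estimated correlation). Their call was lost without ID8-FSHR replicate 2 (0.424), 3 (0.0539) or 4 (0.0504), without uninjected replicate 1 (0.0623), 2 (0.0686) or 3 (0.0578), and with median-of-ratios size factors (0.0553). Oxidative phosphorylation genes rose in 16 of 20 (16 adjusted over the list alone, median 0.35, camera adjusted p = 0.017, and adjusted p = 0.708 with an estimated correlation), with a camera adjusted p of 0.0799 without ID8-FSHR replicate 2. The largest increases were in Pkhd1l1 (1943 ± 910.5 CPM, log2 fold change 10.51, SE 0.42), Tm4sf1, Wt1, Ildr2, Clu, the semaphorin Sema3c, the complement protease C1s1 and the metalloproteinase inhibitor Timp3 (8.84, SE 0.36).

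All 15 B cell genes fell here too (median -2.96, camera adjusted p = 8.68e-16), and B-1 genes fell in 10 of 12 with Myof and Tox higher (median -1.64, camera adjusted p = 0.000233), with the same counts adjusted over the list alone. Both lists had an adjusted p = 0.28 with an estimated correlation. Tox is also on the list of checkpoint and regulatory T cell genes. All 20 ribosomal protein genes fell (20 adjusted over the list alone, median -0.74, camera adjusted p = 2.08e-08, and adjusted p = 0.452 with an estimated correlation), Rps24 from 1206 ± 55.1 to 595 ± 58.1 CPM. Large peritoneal macrophage markers fell in 12 of 18 with Gata6 higher (the same adjusted over the list alone, median -0.98, camera adjusted p = 0.00555, and adjusted p = 0.654 with an estimated correlation). Vsig4, a complement receptor of resident macrophages, fell 4.30-fold, Tgfb2 3.82-fold and the inflammasome sensor Naip1 2.16-fold. MHC class II genes fell in 5 of 12, H2-Eb1, H2-DMb2, H2-Oa, H2-Ob and Cd86, and in 8 without ID8-FSHR replicate 2 (5 adjusted over the list alone, median -0.46, camera adjusted p = 0.00876, and adjusted p = 0.654 with an estimated correlation). The largest decreases were in Cacna1e (log2 fold change -4.22, SE 0.22), Ighv11-2, Igkv14-126, the coagulation factor F13a1 (-3.87, SE 0.42), Il5ra, Diras2, the receptor Tnfrsf8 and Dnase1l3 (-3.72, SE 0.31). Of the 15 lists called, 0 passed with an estimated correlation and 15 with fry.

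Both comparisons use the same uninjected libraries. They shared 9159 genes called in the same direction, 4819 higher and 4340 lower, where independent lists of these sizes would share 1877 and 1625. By contrast 29 genes were called in opposite directions. Simulations with unchanged groups gave 0 shared calls, and splits of the uninjected libraries gave 7582 to 7738. Across genes, which are not independent replicates, the fold changes had a correlation of 0.966 (simulated 0.510, split 0.906 to 0.916) and a covariance of 5.20 (simulated 0.0770, split 5.36 to 5.39), and 88.4% had the same sign (simulated 67.4%, split 84.9% to 86.4%).

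**Figure D2:**
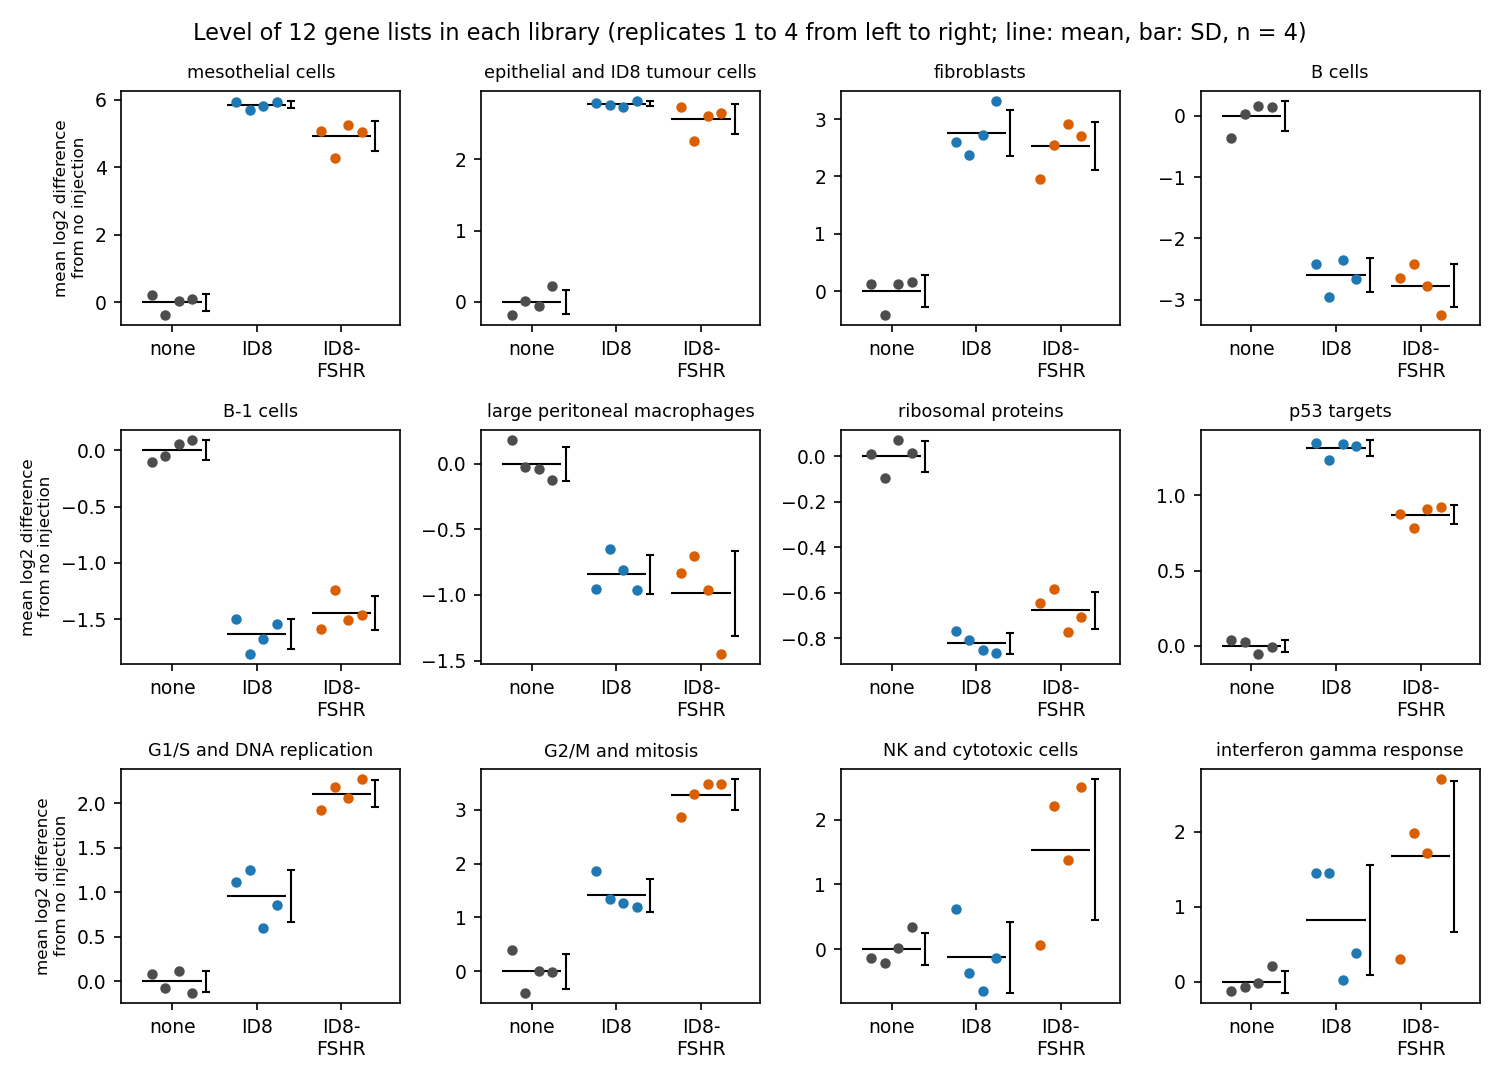
Level of 12 gene lists in each library, as the mean log2 difference from the uninjected mean, with 1 point per library, lines for group means and bars for SD (n = 4). G2/M and mitosis stands at 1.19 to 1.86 in ID8 and 2.87 to 3.49 in ID8-FSHR, and the NK and cytotoxic list at 0.07 in ID8-FSHR replicate 1 and at 1.38 to 2.50 in the other 3 libraries of that group.

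ID8-FSHR against ID8 asks how the cavity differs between mice bearing the 2 lines. Each group received 1 line, so the receptor cannot be told apart from any other difference between the lines. Every tested member of both cell cycle lists and 13 of 14 genes of natural killer (NK) and cytotoxic cells were higher in ID8-FSHR, while 10 of 14 p53 targets and 8 of 15 mesothelial genes were lower. With an estimated correlation the NK list had an adjusted p = 0.624 and the mesothelial list an adjusted p = 0.371, and the NK list's level in ID8-FSHR replicate 1 was 0.07. Ccnb1 (ENSMUSG00000041431.16, chromosome 13, 100778650 to 100786570, minus strand), the cyclin that drives entry into mitosis, stood at 51.2 ± 8.79 CPM against 11.9 ± 3.17 CPM (SD, n = 4 each), a log2 fold change of 2.10 (SE 0.23, edgeR adjusted p = 0.000148). Prex2 (ENSMUSG00000048960.13, chromosome 1, 10993465 to 11303681, plus strand), an exchange factor for the GTPase Rac, stood at 5.94 ± 1.75 CPM against 39.7 ± 5.42 CPM, a log2 fold change of -2.74 (SE 0.28, edgeR adjusted p = 0.000105). In all, 1021 genes were higher and 941 lower of 16915, and the groups did not overlap for 18.5% of the tested genes, where chance gives 2.86%. Leaving out 1 library moved the counts to 555 higher and 406 lower (without ID8 replicate 4), 569 and 466 (ID8 replicate 3), 494 lower (ID8 replicate 1), 636 and 553 (ID8-FSHR replicate 4), and 1731 and 1405 (ID8-FSHR replicate 1). The added genes did not pass the test, with log2 fold changes of -0.50 for Defb29 (SE 0.27, edgeR adjusted p = 0.262) and 0.25 for Vegfa (SE 0.19, edgeR adjusted p = 0.422). Without ID8-FSHR replicate 2 Vegfa was higher by 0.44 (edgeR adjusted p = 0.0407).

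All 20 genes of G2/M and mitosis rose (20 adjusted over the list alone, median 1.91, camera adjusted p = 1.19e-58, and adjusted p = 0.027 with an estimated correlation). Among genes with a mean log2 CPM of at least 3 and groups that do not overlap, the 8 largest increases were genes of mitosis and cytokinesis, with folds of 3.98 to 4.29. Outside these limits some genes rose more, such as the granzyme Gzma (log2 fold change 2.73, edgeR adjusted p = 0.0178), named after its value was seen. They were the cyclins Ccnb1 and Ccnb2, the spindle protein Nusap1 (75.9 ± 10.3 against 18.5 ± 4.91 CPM), the ubiquitin-conjugating enzyme Ube2c, the kinetochore motor Cenpe, the kinesins Kif20a (68.5 ± 15.6 against 17.1 ± 3.82 CPM) and Kif4, and the survivin gene Birc5. All 20 genes of G1/S and DNA replication rose as well (20 adjusted over the list alone, median 1.17, camera adjusted p = 5.17e-43, and adjusted p = 0.027 with an estimated correlation). Without ID8-FSHR replicate 2 all 20 members of each list stayed higher, and both lists had an adjusted p = 0.0508 with an estimated correlation, which ends that call. Tyms stood at 42.2 ± 2.53 against 17.6 ± 1.28 CPM and the histone mRNA binding protein Slbp at 62.9 ± 6.86 against 34.8 ± 2.18 CPM. Nusap1, Ube2c, Kif20a, Kif4 and Slbp share exonic bases with a gene on the other strand, which counting without strand would mix.

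Targets of p53 fell in 10 of 14 genes and rose in 0 (the same adjusted over the list alone, median -0.56, camera adjusted p = 4.47e-07, and adjusted p = 0.0164 with an estimated correlation, or 0.0508 without ID8-FSHR replicate 2). In the same comparison 149 transcripts with 0 counts in every uninjected library, a set chosen after results were seen, had a median log2 fold change of -0.49, with 22 lower and 4 higher. Cdkn1a stood at 105 ± 10.7 against 155 ± 4.30 CPM, the RNA-binding protein Zmat3 at 43.8 ± 6.19 against 69.4 ± 5.35 CPM and the nuclease Aen at 26.0 ± 3.75 against 40.6 ± 3.26 CPM. Mesothelial genes fell in 8 of 15 (10 adjusted over the list alone) and rose in 1, the complement gene C3 (median -1.10, camera adjusted p = 2.34e-06, and adjusted p = 0.371 with an estimated correlation). Igfbp5, which binds insulin-like growth factors, stood at 38.7 ± 11.7 against 156 ± 13.7 CPM, the uroplakin Upk1b at 44.4 ± 16.8 against 146 ± 25.7 CPM and the Wnt pathway ligand Rspo1 at 3.98 ± 0.482 against 9.23 ± 1.31 CPM. ID8-FSHR replicate 2 had the lowest mesothelial level of the tumour libraries, 4.27 on the log2 scale, where the other 3 of its group lay at 5.04 to 5.27 and the ID8 libraries at 5.71 to 5.94. Besides Prex2 and Igfbp5, the largest decreases were in Pcp4l1 (log2 fold change -2.72, SE 0.19), the angiotensin-converting enzyme Ace (13.8 ± 3.90 against 78.1 ± 8.46 CPM, -2.50, SE 0.18). They also took in the protease Prss23, the p53 effector and junction protein Perp (-2.03, SE 0.29), the growth factor Pdgfc and the collagen crosslinking enzyme Lox (-1.88, SE 0.54, edgeR adjusted p = 0.0425). The call of Lox was lost when any of the 8 tumour libraries but ID8-FSHR replicate 1 was left out, at log2 fold changes of -2.13 to -1.60, and with DESeq2 (adjusted p = 0.167) and without a filter (edgeR adjusted p = 0.147).

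Genes of NK and cytotoxic cells rose in 13 of 14 (14 adjusted over the list alone, median 2.05, camera adjusted p = 4.44e-09, and adjusted p = 0.624 with an estimated correlation). Eomes, a transcription factor of NK cells, stood at 11.4 ± 6.54 against 2.80 ± 0.801 CPM, the NK receptor Klre1 at 5.63 ± 3.12 against 1.33 ± 0.590 CPM and the granule protein gene Nkg7 at 13.1 ± 7.32 against 3.60 ± 1.40 CPM. The list's level was 0.07 in ID8-FSHR replicate 1 and -0.64 to 0.62 in the ID8 libraries. Without single libraries the 13 became 7 (ID8 replicate 2), 5 (ID8 replicate 3), 6 (ID8 replicate 4), 5 (ID8-FSHR replicate 2) and 5 (ID8-FSHR replicate 4). In a fit of the 8 tumour libraries alone 6 of the 14 passed (median 2.07, camera adjusted p = 5.32e-08), and 0 with the Defb29 level added to that fit as a covariate (median 1.66, camera adjusted p = 0.00186). The Defb29 level went partly with the group, at 4.41 to 4.89 log2 CPM in ID8 and 3.16 to 4.60 in ID8-FSHR. The loss of these calls came with a smaller median, and how much of it is lost power cannot be told. T cell genes rose in 6 of 16, Cd3e, Cd3g, Lck, Trbc2, Cd28 and Cd5 (13 adjusted over the list alone, median 1.08, camera adjusted p = 3.96e-07, and adjusted p = 0.714 with an estimated correlation). Cd3e, Cd3g and Trbc2 were named after their values were seen. In the fit of the 8 tumour libraries alone 11 of the 16 passed (median 1.10, camera adjusted p = 6.34e-11). With the Defb29 covariate added 6 passed (median 0.76, camera adjusted p = 8.18e-07). The costimulatory receptor Cd28 stood at 2.59 ± 0.742 against 0.930 ± 0.279 CPM. The 6 called with all 12 libraries became 3 without ID8 replicate 1, and 2 without ID8 replicate 2, 3 or 4 or ID8-FSHR replicate 2 or 4. Lck was not called without these last 5, at log2 fold changes of 1.10 to 1.34, nor with limma-voom (adjusted p = 0.0513) or without a filter (edgeR adjusted p = 0.0792).

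Checkpoint and regulatory T cell genes rose in 6 of 20, Ctla4, Tigit, Tox, Foxp3, Tnfrsf9 and Entpd1 (12 adjusted over the list alone, median 0.96, camera adjusted p = 2.76e-05, and adjusted p = 0.714 with an estimated correlation). Tigit, Tnfrsf9 and Entpd1 were named after their values were seen. Tox, a transcription factor of activated and exhausted T cells, stood at 3.23 ± 1.20 against 0.835 ± 0.289 CPM, and Foxp3, the lineage factor of regulatory T cells, at 5.61 ± 1.64 against 2.08 ± 0.628 CPM. Of the 4577 exonic bases of Foxp3, 853 are shared with genes on the same strand. The 6 became 2 without ID8 replicate 3 or 4 or ID8-FSHR replicate 4, 3 without ID8-FSHR replicate 2 and 16 without ID8-FSHR replicate 1. Ctla4 was not called without ID8 replicate 3 or 4 or ID8-FSHR replicate 4, at log2 fold changes of 1.62 to 1.63, nor in the fit of only the groups compared (edgeR adjusted p = 0.0567). Interferon gamma response genes had a median of 0.90 and 0 of 18 were called by edgeR, 0 adjusted over the list alone and 12 without ID8-FSHR replicate 1 (camera adjusted p = 0.00109, and adjusted p = 0.791 with an estimated correlation). Without ID8-FSHR replicate 4 their median was 0.51, with 0 called. MHC class I genes rose in 2 of 14, H2-Q6 and H2-Q7, in 6 adjusted over the list alone and in 9 without ID8-FSHR replicate 1 (median 0.59, camera adjusted p = 0.00109, and adjusted p = 0.791 with an estimated correlation). H2-Q7 stood at 71.6 ± 31.4 against 30.1 ± 8.69 CPM and H2-Q6 at 84.4 ± 34.9 against 40.9 ± 9.67 CPM. These are near-identical copies and uncertain. Neither was called without ID8 replicate 3 or 4 or ID8-FSHR replicate 2 or 4 (log2 fold changes of 1.05 to 1.17 and 0.82 to 0.96), without a filter (edgeR adjusted p = 0.0783 and 0.0915) or in the fit of only the groups compared (edgeR adjusted p = 0.0542 and 0.0629). H2-Q4 had a log2 fold change of 0.80 (edgeR adjusted p = 0.056) and was called higher without ID8-FSHR replicate 1 (1.02, edgeR adjusted p = 0.00353), without ID8 replicate 2 (0.94, edgeR adjusted p = 0.049) and with DESeq2 (0.79, adjusted p = 0.0106).

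The remaining called lists moved little. Ribosomal protein genes had a median of 0.14 with 1 riser, Rps2 (1 adjusted over the list alone, camera adjusted p = 0.00234). Oxidative phosphorylation genes had a median of 0.18 with 1 riser, Ndufs3 (0 adjusted over the list alone, camera adjusted p = 0.00956, and 0.0502 without ID8 replicate 3), and 4 risers without ID8-FSHR replicate 1. Hypoxia and glycolysis genes had a median of 0.38, with Pgk1 and Pkm higher and Egln3 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.0202). That call was lost without ID8 replicate 3 (0.0821), ID8-FSHR replicate 2 (0.0731) or ID8-FSHR replicate 4 (0.0874), and 10 rose without ID8-FSHR replicate 1, 4 without ID8 replicate 2, 1 without ID8-FSHR replicate 2 and 0 without ID8 replicate 1, 3 or 4 or ID8-FSHR replicate 4. Mast cell genes had a median of -0.42 with 1, Mcpt4, lower (1 adjusted over the list alone, camera adjusted p = 0.0253), a call lost without ID8 replicate 2 (0.108), ID8 replicate 3 (0.0502), ID8-FSHR replicate 3 (0.108) or ID8-FSHR replicate 4 (0.152). These 4 lists had an adjusted p = 0.791 with an estimated correlation. In a fit of the 8 tumour libraries alone hypoxia (camera adjusted p = 0.0454), oxidative phosphorylation (0.0201), ribosomal protein (0.00945), interferon gamma (0.00502), MHC class I (0.00574) and checkpoint genes (9.98e-05) stayed called. With the Defb29 level added to that fit as a covariate they were not (camera adjusted p = 0.434, 0.193, 0.114, 0.341, 0.392 and 0.114). In the same order their medians went from 0.40, 0.20, 0.16, 0.93, 0.61 and 0.98 to 0.12, 0.12, 0.11, 0.58, 0.27 and 0.38. The lost calls thus came with smaller differences. Since the Defb29 level went partly with the group, lost power and differences that go with that level cannot be told apart. The FSH and cAMP list was not called between the tumour groups, with a median of 0.07 while camera pointed lower (camera adjusted p = 0.6), and 1 of 19 genes fell, the coactivator Ppargc1a (0 adjusted over the list alone). Of the 13 lists called, 3 passed with an estimated correlation (both cell cycle lists and p53 targets) and 4 with fry. Without ID8-FSHR replicate 2 those 3 had an adjusted p = 0.0508 with an estimated correlation.

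**Figure D3:**
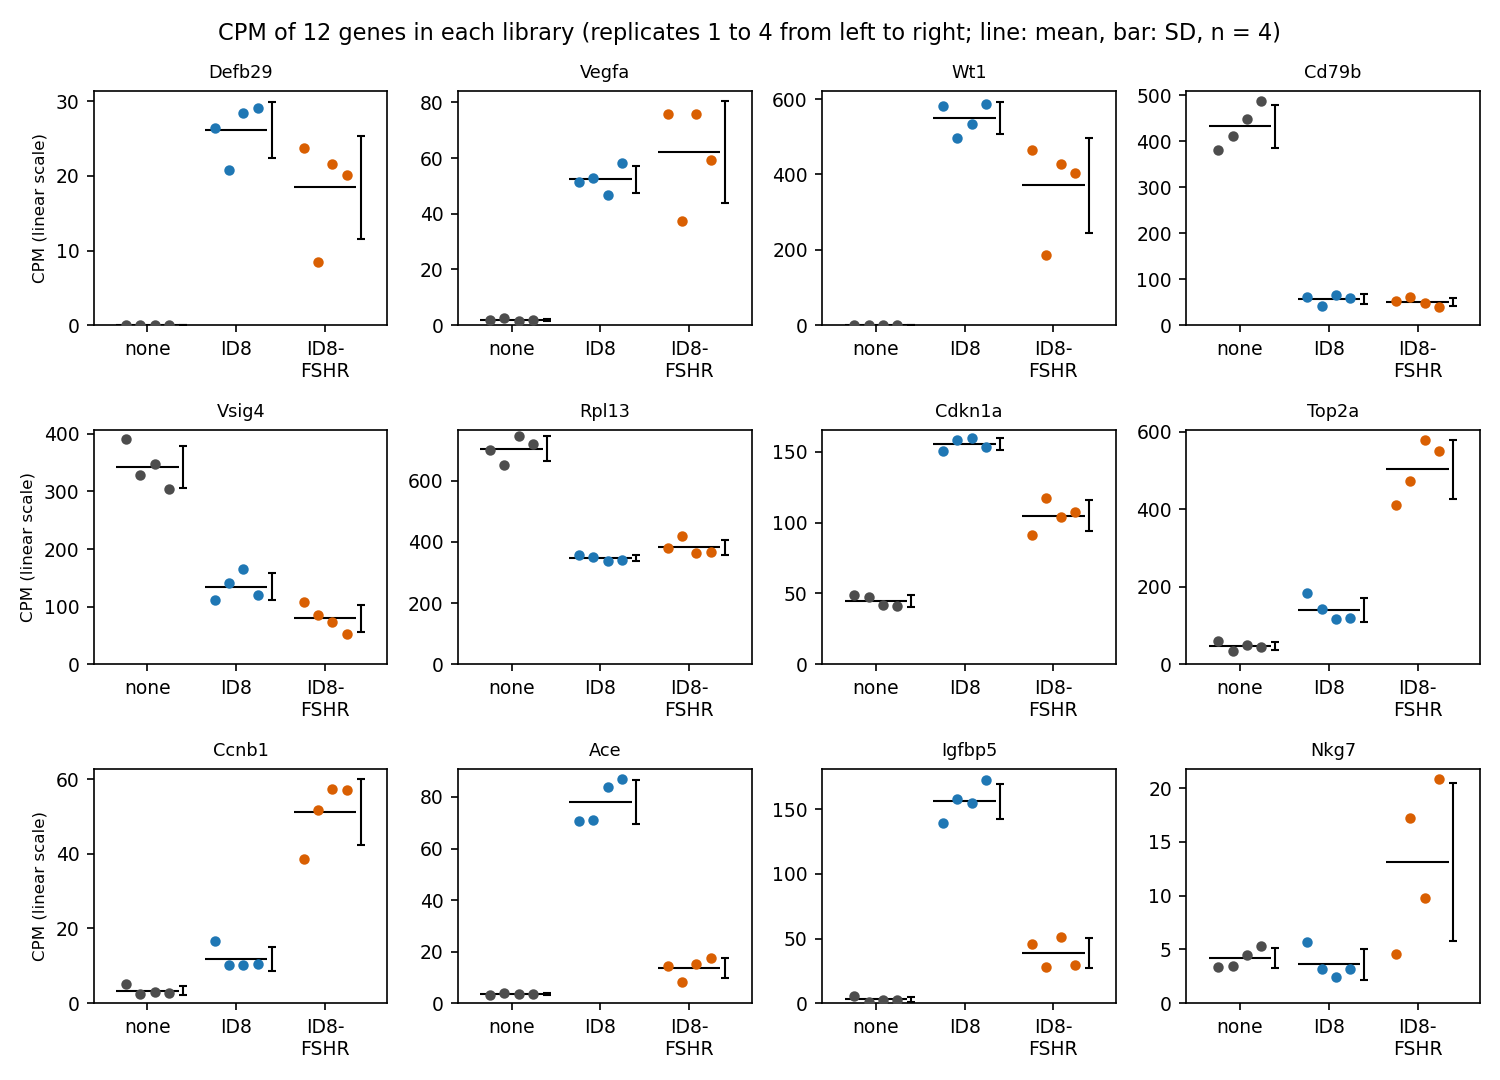
CPM of 12 named genes in each library on linear axes that start at 0, with 1 point per library, lines for group means and bars for SD (n = 4). Ccnb1 stands at 11.9 ± 3.17 CPM in ID8 and 51.2 ± 8.79 CPM in ID8-FSHR, and Ace at 78.1 ± 8.46 and 13.8 ± 3.90 CPM.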

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

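Tests written before their result was seen are the NK and erythroid covariate tests, the label swap, the mislabelled library and the spread of immune lists. Those chosen after results had been seen are the T cell covariate test, the tumour transcript tests, the fits without ID8-FSHR replicate 2, the total count, the wrong label on ID8-FSHR replicate 1, the macrophage and B cell markers and the regrouping of libraries. The genes and lists named below came up through rules applied to all named genes and lists.

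The 40 cell cycle genes had a median log2 fold change of 1.61 in ID8-FSHR versus ID8 (quartiles 1.18 and 1.91). Hypothesis: a larger share of tumour cells in the ID8-FSHR libraries. The 149 transcripts with 0 counts in all uninjected libraries and a mean of at least 1 CPM had a median of -0.49 (quartiles -0.91 and 0.01), in the other direction. That argues against a larger share only if both lines express these transcripts alike. Whether they do was not tested, so a larger share is not excluded. ID8-FSHR replicate 2 alone is excluded since 40 of the 40 genes stayed higher without it. Hypothesis: more NK cells that divide. With the NK list level as a covariate in the 8 tumour libraries the median was 1.16 (quartiles 0.89 and 1.44). Of the 40 genes 25 were called, where 39 were called without it. The NK level ran from -0.64 to 0.62 in ID8. It was 0.07 in ID8-FSHR replicate 1 and 1.38 to 2.50 in the other libraries of that group. Only 1 ID8-FSHR library thus lay within the ID8 range, and this test cannot exclude the hypothesis as a whole or partial cause. All genes called, of the 16915 kept over all 12 libraries, went from 1326 to 204 and the NK median from 2.05 to 0.02 with that covariate, and no test here separates lost power from differences that go with the NK level. Hypothesis: more T cells that divide; the T cell list level ran from -0.54 to 0.45 in ID8-FSHR and from -1.06 to -0.84 in ID8, so as a covariate (median 1.31, quartiles 1.06 and 1.84, with 4 genes called) it cannot be told apart from the group.

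ID8-FSHR replicate 2 lay nearest the uninjected libraries. Hypothesis: it holds a smaller share of tumour cells; on log2 of CPM plus 0.5, the scale used first, the 149 tumour transcripts lay at a median of -0.83 from the other 3 libraries of its group (quartiles -1.13 and -0.61, with 98.7% of them lower), short of the bound of -1, so this test cannot tell. On edgeR's log CPM, a scale tried after the first result was seen, the median was -1.08 (quartiles -1.41 and -0.79). The shifts of 11 immune lists in it, 10 of them upward, had an SD of 0.339 and ran from -0.01 (plasma cells) to 1.06 (eosinophils), where the SD in the other 7 tumour libraries ran from 0.251 to 0.639, so a common dilution fits by the bound set and the shifts were not all alike. Hypothesis: a mislabelled ID8 library. It lay nearer the other ID8-FSHR libraries in 78.1% of 959 genes that were higher without it. The share was 87.6% for 728 that were lower (of 735, the others being outside the 16915 genes tested with all libraries). A smaller share of tumour cells could also give part of these shares. Its G2/M and mitosis level was 3.30, against 1.19 to 1.86 in ID8 and -0.40 to 0.40 in uninjected libraries. Mixing an ID8 library with uninjected cells would not give that level, which argues against a mislabelled ID8 library. Fewer reads are excluded, with a total of 49886419 inside the range of its group.

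NK and cytotoxic genes were high in ID8-FSHR replicates 2 to 4 and not in replicate 1. Hypothesis: the labels of ID8 replicate 2 and ID8-FSHR replicate 1 were swapped. Over 3097 genes called without both, ID8 replicate 2 lay nearer its own group in 76.2%, which argues against a swap. ID8-FSHR replicate 1 lay nearer its own in 47.5%, which a swap could also give. These shares alone therefore do not exclude a swap. A test for a wrong label on ID8-FSHR replicate 1 alone was added after those shares were seen. It found that library above every ID8 library in 40 of 40 cell cycle genes. That argues against a wrong label, though these genes were called in a fit that used the label. Hypothesis: blood in the lavage; with the erythroid list level as a covariate the NK median was 1.94 (quartiles 1.71 and 2.25, 2 genes called against 6 without it), which excludes it. Hypothesis: a lower share of tumour cells in ID8-FSHR. The 33 macrophage and B cell markers had a median of -0.14 (quartiles -0.29 and 0.18) against 2.05 for NK genes (quartiles 1.83 and 2.36). That argues against it as the sole cause, if these markers kept their share among host cells, which was not tested. A partial cause is not excluded.

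The 8 libraries of each comparison were also regrouped. The real grouping is 1 of only 35, so this test cannot exclude chance. Against no injection, mixed groupings put the large difference between groups inside each side, so their counts were bound to be low. Of the 35 ways to divide 8 libraries into 4 and 4, only 1, the real grouping, called as many genes as it did. It called 10847 genes for ID8 and 10913 for ID8-FSHR against no injection, with 0 as the highest count of any other grouping. For ID8-FSHR versus ID8 it called 1962, and the highest other count was 240, from the grouping that exchanges ID8 replicate 2 and ID8-FSHR replicate 1, the swap weighed for NK genes; the remaining groupings called 0.

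A library stood far from the other 3 of its group in 18 of the 405 groups of 4 values checked, where 20.25 are expected by chance at 1 in 20. Fshr was at 0.0398 CPM in ID8 replicate 3 and 0 in the others. Tm4sf1 was at 0.996 CPM in uninjected replicate 2 (others 0.0404 to 0.174). Wt1 was at 0.741 CPM in uninjected replicate 4 (others 0.283 to 0.296). Ildr2 was at 225 CPM in ID8-FSHR replicate 2 (others 544 to 596). Cacna1e was at 10.0 CPM in ID8 replicate 2 (others 17.2 to 18.4). Bhlhe41 was at 18.2 CPM in ID8-FSHR replicate 4 (others 15.4 to 15.8). Siglecg was at 196 CPM in uninjected replicate 4 (others 159 to 162). Phlda3 was at 3.14 CPM in uninjected replicate 1 (others 1.78 to 1.96). Tnfrsf8 was at 52.5 CPM in uninjected replicate 2 (others 26.1 to 29.6). Nr5a1 was at 0.218 CPM in uninjected replicate 4 and 0 in the others. Ccnb1 was at 16.7 CPM in ID8 replicate 1 (others 10.2 to 10.5). Ube2c was at 31.3 CPM in ID8-FSHR replicate 1 (others 55.0 to 58.7). Klre1 was at 2.21 CPM in ID8 replicate 1 (others 0.956 to 1.17). Cd28 was at 1.85 CPM in uninjected replicate 1 (others 2.97 to 3.06). On the log2 list scale, neutrophil genes were at 1.41 (others -0.28 to -0.06), unfolded protein response genes at 0.78 (others 0.45 to 0.48) and p53 targets at 1.24 (others 1.33 to 1.35) in ID8 replicate 2, and fibroblast genes at -0.41 in uninjected replicate 2 (others 0.12 to 0.16). Against no injection 29 genes were called in opposite directions in the tumour groups, each with a called difference between them. Tox had the log2 fold change of 1.94 in ID8-FSHR versus ID8. Fshr, below the filter, had 7 counts in ID8-FSHR replicate 4.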

How the results depend on the processing

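The alternatives were fixed before the files were opened, except the Defb29 covariate, the list tests over the 8 tumour libraries and the list tests without ID8-FSHR replicate 2, which were chosen after results had been seen. No setting reversed the direction of a named gene or a called list, but the balance of higher and lower genes did turn. For ID8-FSHR versus ID8, with 1021 higher and 941 lower, it was 979 and 1262 with limma-voom, 1445 and 1472 with DESeq2 and 1034 and 1040 with the filter of 1 CPM in 4 libraries. That filter also gave 4693 and 4922 in ID8 versus no injection, where 5537 were higher and 5310 lower. With a fold of at least 2 required, 3281 genes were higher and 2128 lower in ID8 versus no injection, 3343 and 2022 in ID8-FSHR versus no injection and 412 and 260 in ID8-FSHR versus ID8, and 4437 were shared. An adjusted p under 0.01 left 428 higher and 279 lower in ID8-FSHR versus ID8. In that comparison the fit of only the groups compared (the 8 tumour libraries, with 16094 genes after their own filter) called 746 higher and 604 lower, and the same fit with the Defb29 level as a covariate 911 higher and 526 lower. Leaving out 1 library gave 555 to 1731 higher and 406 to 1405 lower there, with the lowest counts without ID8 replicate 4 (555 and 406) and ID8 replicate 3 (569 and 466), then 494 lower without ID8 replicate 1 and 636 and 553 without ID8-FSHR replicate 4, and the highest without ID8-FSHR replicate 1 (1731 and 1405). Without ID8-FSHR replicate 2 the counts were 959 and 735. With a block for the replicate number the counts were 5404 and 5177, 5574 and 5092, and 860 and 916, with 8953 shared; libraries of the same number were not alike beyond their group, since 1 of 12 such pairs had a correlation over 0.1 (range -0.11 to 0.19) and 2 of 12 libraries went best with their own number. Of the 122 tests of named genes, 120 kept their label with DESeq2, 121 with limma-voom, 118 without a filter and 119 with only the groups compared; Lox was lost with DESeq2 (-1.89) and H2-Q4 gained (0.79). Of the 41 list calls, 3 held with an estimated correlation, 32 with fry, 39 with median-of-ratios size factors and 40 with the block, where type I interferon genes in ID8-FSHR had an adjusted p of 0.103. With the Defb29 covariate in those 8 libraries 7 of the 13 calls in ID8-FSHR versus ID8 held; lost were interferon gamma (adjusted p = 0.341 with camera), MHC class I (0.392), checkpoint (0.114), hypoxia (0.434), oxidative phosphorylation (0.193) and ribosomal protein genes (0.114), which all held in the 8 libraries without it, and NK genes called higher went from 13 with all 12 libraries to 6 with the 8 and 0 with the covariate. The medians of the lost lists fell with that covariate. Over all genes the calls went from 746 to 911 higher and from 604 to 526 lower. The Defb29 level went partly with the group, so lost power and differences that go with that level cannot be told apart. The list tests without ID8-FSHR replicate 2 ended some calls in ID8-FSHR versus no injection. These were fibroblast (0.0799), type I interferon (0.424), extracellular matrix (0.123) and oxidative phosphorylation genes (0.0799). In ID8-FSHR versus ID8 hypoxia genes were no longer called (0.0731), while B cell (0.0426), unfolded protein response (0.0382) and immediate early genes (0.0171) were called lower. Both cell cycle lists and p53 targets then had an adjusted p of 0.0508 with an estimated correlation, so 0 lists passed that test in this comparison.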

Other observations

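The gene lists below were fixed before the files were opened, and the members named as examples were chosen after their values were seen. Against no injection, more interferon response genes were higher than lower in both tumour groups, and neither interferon list was called in ID8. Type I interferon response genes rose in 16 of 22 and fell in 0 in ID8 (16 adjusted over the list alone, camera adjusted p = 0.145). Between the tumour groups 0 of 22 passed (median 0.49, camera adjusted p = 0.146), and 8 did without ID8-FSHR replicate 1, while without ID8-FSHR replicate 4 the median was -0.02 with 0 called. Interferon gamma response genes rose in 8 of 18 in ID8, with Ciita and Ido1 lower (camera adjusted p = 0.713), and in 13 of 18 in ID8-FSHR (median 1.53, camera adjusted p = 0.22). The type I interferon level was 0.37 in ID8-FSHR replicate 1 and 1.80 to 2.82 in the other libraries of its group. MHC class I genes had 1 higher and 3 lower in ID8 (1 and 2 adjusted over the list alone, camera adjusted p = 0.605) and 5 higher in ID8-FSHR, Tap1, Tapbp, H2-T22, Erap1 and Psmb10 (camera adjusted p = 0.662), or 10 without ID8-FSHR replicate 1. T cell genes fell in 13 of 16 in ID8 (14 adjusted over the list alone, 8 without uninjected replicate 2, camera adjusted p = 0.0502) and in 1 of 16 in ID8-FSHR (0 adjusted over the list alone, camera adjusted p = 0.665). NK and cytotoxic genes had 1 higher, Gzmb, and 1 lower, Ccl5, in ID8 (0 and 0 adjusted over the list alone, camera adjusted p = 0.605), or 0 and 3 without ID8 replicate 1, and 11 of 14 higher in ID8-FSHR (median 2.00, camera adjusted p = 0.232). Checkpoint and regulatory T cell genes had 1 higher and 9 lower of 20 in ID8 (camera adjusted p = 0.123), and 9 higher and 6 lower in ID8-FSHR, with a median of 0.43 where camera pointed lower (camera adjusted p = 0.697).

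Small peritoneal macrophage and monocyte genes had 1 higher and 8 lower of 16 in ID8 (camera adjusted p = 0.084). In ID8-FSHR 4 were higher, Ly6c2, Fcgr1, Cx3cr1 and Chil3, and 6 lower (camera adjusted p = 0.155). Between the tumour groups 4 were higher, among them the monocyte antigen Ly6c2, Clec4e and Ms4a4c, and 1 lower, F13a1 (5 and 2 adjusted over the list alone, camera adjusted p = 0.376). Those 4 became 0 without ID8 replicate 3 or 4, 1 without ID8 replicate 1 or ID8-FSHR replicate 2 or 4, and 2 without ID8 replicate 2 or ID8-FSHR replicate 3. Alternative activation genes had 3 higher and 6 lower of 17 in ID8, with arginase Arg1, Tgm2 and Gpnmb higher (camera adjusted p = 0.605). They had 6 higher and 7 lower in ID8-FSHR (camera adjusted p = 0.663, with 4 lower without ID8-FSHR replicate 3 or uninjected replicate 3), and between the tumour groups 1 lower, Cd163 (camera adjusted p = 0.607), with 3 higher without ID8-FSHR replicate 1. Inflammatory cytokine genes had 5 higher, Il6, Cxcl3, Ccl12, Ptgs2 and Csf1, and 2 lower, Tnf and Nlrp3, of 19 in ID8 (3 and 2 adjusted over the list alone, camera adjusted p = 0.881). In ID8-FSHR 9 were higher and 1 lower (camera adjusted p = 0.582), and 1, Csf1, lower between the tumour groups (camera adjusted p = 0.146), with 3 higher without ID8-FSHR replicate 1. The 5 in ID8 became 3 without ID8 replicate 2 or uninjected replicate 2. Complement genes had 3 higher, C1ra, C1s1 and Serping1, and 9 lower of 15 in ID8 (camera adjusted p = 0.436). In ID8-FSHR 5 were higher and 9 lower (camera adjusted p = 0.4), and 2 and 2 between them (4 and 3 adjusted over the list alone, camera adjusted p = 0.848), or 4 and 2 without ID8-FSHR replicate 1 and 0 and 0 without ID8 replicate 3 or ID8-FSHR replicate 2. Of 6 endothelial genes 3 rose and 2 fell in each tumour group (camera adjusted p = 0.61 in ID8 and 0.586 in ID8-FSHR) and 0 passed between them (camera adjusted p = 0.949).

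Among the 29 genes that moved in opposite directions, the retrotranslocation factor Derl3 rose by 1.42 in ID8 and fell by 1.24 in ID8-FSHR on the log2 scale, Rab3b rose by 1.41 and fell by 1.09, the Notch ligand Jag1 rose by 0.66 and fell by 0.33, and the nuclear RNA Malat1 rose by 0.75 and fell by 0.32. The histone variant gene H2az1 fell by 0.38 in ID8 and rose by 0.51 in ID8-FSHR, Dek fell by 0.26 and rose by 0.42, and Tox fell by 1.07 and rose by 0.87. Xist (ENSMUSG00000086503.4, chromosome X, 103460366 to 103483254), the RNA of the inactive X, fell from 1391 ± 156 CPM to 404 ± 38.0 in ID8 (log2 fold change -1.78) and 521 ± 205 in ID8-FSHR (-1.42), with 0.37 between the tumour groups (edgeR adjusted p = 0.267). It was the only tested member of the list of sex-linked check genes. The list of the line's added genes had 2 tested members, Defb29 and Vegfa, both higher against no injection (medians 9.10 and 8.98, or 7.76 and 7.65 with all-zero groups at their bound), and 0 passed between the tumour groups (median -0.13).

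Other lists were not called against no injection. Neutrophil genes had 1 higher and 2 lower of 14 in ID8 (0 and 2 adjusted over the list alone, median 0.41 where camera pointed lower, camera adjusted p = 0.701). Without uninjected replicate 2 there were 3 higher (median 1.16), and without ID8 replicate 2 there were 0 (median -0.58). In ID8-FSHR they had 3 and 2 (1 and 2 adjusted over the list alone, median 0.45, camera adjusted p = 0.692), with 5 higher without uninjected replicate 2 (median 1.18) and 1 without another uninjected library or ID8-FSHR replicate 2. Between the tumour groups 0 passed (median -0.21 where camera pointed higher, camera adjusted p = 0.949), with 1 higher and a median of 0.74 without ID8 replicate 2. Plasma cell genes had 4 higher and 5 lower of 9 in ID8 (camera adjusted p = 0.393). In ID8-FSHR they had 1 and 5 (1 and 6 adjusted over the list alone, camera adjusted p = 0.0921) and 0 and 3 between them (1 and 3 adjusted over the list alone, camera adjusted p = 0.0523), with 1 lower when any ID8 library or ID8-FSHR replicate 4 was left out; in the 8 tumour libraries alone the list was called lower (0.0427). Mast cell genes had 1 and 8 of 14 in ID8 (camera adjusted p = 0.381, with 2 or 3 lower without ID8 replicate 1 or 4 or uninjected replicate 1 or 2) and 1 and 9 in ID8-FSHR (camera adjusted p = 0.0712). Eosinophil genes had 0 and 2 of 6 in ID8 (camera adjusted p = 0.248). They had 1 and 3 in ID8-FSHR (median 0.05 where camera pointed lower, camera adjusted p = 0.322, or 4 and 1 without ID8-FSHR replicate 3 and 2 and 1 without uninjected replicate 1) and 0 between them (camera adjusted p = 0.61). Dendritic cell genes had 1 and 8 of 13 in ID8 (camera adjusted p = 0.085). They had 2 and 7 in ID8-FSHR (camera adjusted p = 0.0792) and 0 and 1 between them (0 and 2 adjusted over the list alone, camera adjusted p = 0.949). Erythroid genes had 1 lower of 7, Tal1, in each tumour group (medians 1.67 and 1.86 where camera pointed lower, camera adjusted p = 0.881 and 0.72). Between those groups 0 passed (median 0.26 where camera pointed lower, camera adjusted p = 0.729), and the median was -3.68 without ID8-FSHR replicate 3 and 1.23 without ID8 replicate 2. Haemoglobin genes took 0.0216% of counts in ID8 replicate 2 and 0.0369% in ID8-FSHR replicate 3. Megakaryocyte genes had 1 higher, Itga2b, and 1 lower, Pf4, of 3 in each (camera adjusted p = 0.727 and 0.494) and 0 between them (0 and 1 adjusted over the list alone, camera adjusted p = 0.28). Adipocyte genes had 1 and 2 of 4 in each (camera adjusted p = 0.393 and 0.375) and 0 between them (1 and 1 adjusted over the list alone, camera adjusted p = 0.838).

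Among gene groups, lipid handling genes had 3 higher and 10 lower of 16 in ID8 (camera adjusted p = 0.161) and 3 and 8 in ID8-FSHR (camera adjusted p = 0.102). Between them 2 were lower, the apolipoprotein Apoe and Cd63 (median 0.02 where camera pointed lower, camera adjusted p = 0.729). Cholesterol synthesis genes had 7 and 2 of 19 (camera adjusted p = 0.516), 7 and 1 (camera adjusted p = 0.334) and 0 (camera adjusted p = 0.432) in the same order of comparisons. Hypoxia and glycolysis genes had 6 and 3 of 19 in ID8 (camera adjusted p = 0.628) and 12 and 2 in ID8-FSHR (camera adjusted p = 0.22). Angiogenesis genes had 7 and 4 of 15 in ID8 (7 and 5 adjusted over the list alone, camera adjusted p = 0.443). They had 7 and 3 in ID8-FSHR (camera adjusted p = 0.375) and 0 between them (camera adjusted p = 0.949). Oxidative phosphorylation genes had 9 higher of 20 in ID8 (camera adjusted p = 0.162). Unfolded protein response genes had 8 and 3 of 14 in ID8 (9 and 3 adjusted over the list alone, camera adjusted p = 0.43). In ID8-FSHR they had 6 and 4 (camera adjusted p = 0.727, with 2 lower without ID8-FSHR replicate 1, 3 or 4) and 3 lower between them (camera adjusted p = 0.146), where the list was called lower without ID8-FSHR replicate 2 (0.0382) and, in the 8 tumour libraries, with the Defb29 covariate (0.0112) but not without it (0.277). Immediate early genes had 2 and 7 of 20 in ID8 (camera adjusted p = 0.396), 2 and 8 in ID8-FSHR (camera adjusted p = 0.109) and 1, Btg2, lower between them (camera adjusted p = 0.0938), or 3 without ID8-FSHR replicate 1. Immediate early genes were called lower there without ID8-FSHR replicate 2 (camera adjusted p = 0.0171) and, in the 8 tumour libraries, with the Defb29 covariate (0.00389) but not without it (0.0984). Mitochondrial transcripts had 1 and 6 of 15 in ID8 (camera adjusted p = 0.258), 1 and 4 in ID8-FSHR (camera adjusted p = 0.374) and 0 between them (camera adjusted p = 0.432). Between the tumour groups, large peritoneal macrophage genes had 1 higher, Serpinb2, and 3 lower, Cxcl13, Vsig4 and Tgfb2, of 18 (1 and 5 adjusted over the list alone, median 0.18 where camera pointed lower, camera adjusted p = 0.795). Without ID8 replicate 3 these were 0 and 0, without ID8 replicate 4 or ID8-FSHR replicate 2 or 3 they were 0 and 1, and without ID8-FSHR replicate 4 they were 3 and 2. In the same comparison B cell genes had 0 of 15 (median -0.18, camera adjusted p = 0.348), and the list was called lower without ID8-FSHR replicate 2 (median -0.28, camera adjusted p = 0.0426). B-1 genes had 3 higher, Cd5, Ctla4 and Tox, and 1 lower, Apoe, of 12 (4 and 1 adjusted over the list alone, median -0.02 where camera pointed higher, camera adjusted p = 0.454). Cd5 is also on the T cell list, and Ctla4 and Tox are also on the checkpoint list. Epithelial and ID8 tumour genes had 1 and 3 of 13 (camera adjusted p = 0.407) and fibroblast genes 1 higher, Thy1, of 13 (camera adjusted p = 0.795). Extracellular matrix genes had 3 lower of 18, Col6a2, Lox and Ccn2 (6 adjusted over the list alone, camera adjusted p = 0.174), but 0 or 1 without any single library other than ID8-FSHR replicate 1, and 5 without that library. That list was called lower in the 8 tumour libraries alone (camera adjusted p = 0.00945), and there with the Defb29 covariate (0.0054). MHC class II genes had 0 of 12 (camera adjusted p = 0.0938), or 8 without ID8-FSHR replicate 1.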
